A study of Mus musculus with 2 samples.

How the data were processed

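Trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark of active and poised promoters, was measured by chromatin immunoprecipitation and sequencing in the heart of the mouse embryo at day 12.5. Per the labels, the tissue came from B6NCrl embryos of both sexes, pooled, and there were 2 biological replicates with 1 library each, which form a single group. The series holds no second condition, so no comparison between groups was made. The comparisons are those between the replicates, between peaks and the genome annotation, and between lists of genes.

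Each replicate had a deposited peak list, and 2 further lists covered both replicates: a pooled list, and a replicated list that the accompanying text describes as derived from the pooled list and both replicates' lists. The coordinates are on mm10, per the labels. The aligner, the peak caller, its thresholds and the rule behind the replicated list are not given in the sources used here. Each peak carries a score from the authors, a display value of the peak format that was not used. Each peak also carries a signal value from the authors, whose scale is not stated in the accompanying text, and the deposited −log10 p and −log10 q of the peak. No peak in any of the 4 lists had a −log10 p below 2, which was read from the values. The signal and the −log10 q were used only to rank or filter peaks within a list. Control libraries were not analysed here. Peak lists hold no read counts, so the depth of each library is unknown, and no interval that needs depth is given. A weak peak missing from 1 list therefore says only that it was not called there.

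Peaks on the assembled chromosomes were used for regions and genes, leaving out 11 replicated peaks on unplaced or unlocalized scaffolds. The GENCODE M21 annotation and the RefSeq annotation of the same assembly (GRCm38, the assembly behind mm10) were available, and 0 chromosomes had a peak past their end in the reference. Peaks of a list separated by at most 1000 bp were merged into regions. A protein-coding gene was called marked when a peak lay within 1000 bp of any start site of its protein-coding transcripts, and its domain was the widest merged region holding such a peak. This rule lets a gene take its domain from an internal start site or share it with a neighbour. Main results use the replicated list, and the leading values are also given from each replicate's own list as mean ± SD with n = 2. Widths depend on the caller's thresholds and on the merging gap, so they are compared only within a list.

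A total of 22 gene lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined. They include 9 lists for cell types and functions of the heart (cardiac transcription factors, sarcomere, calcium handling and conduction, heart signalling, endothelial and endocardial, epicardial, cushion mesenchyme and fibroblast, smooth muscle and pericyte, neural crest and Schwann cell). Markers of other tissues that a dissection could hold (erythroid, leukocyte, hepatocyte, neuronal, lung and foregut, skeletal muscle, germline, olfactory receptors), patterning genes (neural patterning factors, Hox) and broadly expressed genes (cell cycle, mitochondrial energy metabolism, housekeeping) made up the rest. Named genes are the 4 marked members of each list with the widest domains and up to 3 unmarked members in alphabetical order, any member of the cardiac transcription factor, sarcomere and epicardial lists, the 20 genes with the widest domains, the 10 widest regions over 10 kb from any start site, and the 5 genes of highest signal among those marked in 1 replicate only. Genes named in the additional observations were chosen after their values were seen.

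The share of marked genes in a list was compared with all other protein-coding genes by a two-sided Fisher's exact test. Domain width was compared by a two-sided permutation test of the mean rank of the marked members among all marked genes, with 100000 random sets of the same size, for lists with at least 3 marked members. Membership of the widest 5% of start-site domains was compared by Fisher's exact test. All p-values over lists were adjusted by the Benjamini-Hochberg method within each of these families, at a threshold of 0.05. Genes are not independent replicates, so these tests describe lists of genes in this group and say nothing of other embryos. Extension around the start site was tested by a two-sided permutation test that flips the sign of the difference per gene, and CpG content by a permutation test of the difference in medians. The CpG ratio is the observed count of CpG over that expected from C and G within 1000 bp of each start site, averaged over a gene's start sites. Chance overlap came from 100 random placements of regions on the same chromosomes outside assembly gaps. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and matplotlib 3.10.9 for the figures.

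The list tests were tested on simulated data, with 200 changed and 200 unchanged lists of 20 genes drawn from 21853 genes. At a raw p under 0.05, the test of the share marked called 189 of the changed lists, made with 98% against 67% marked, and 7 of the unchanged lists. The test of domain width called 184 lists made 2 times as wide, and 9 of the unchanged lists. The simulation marked genes independently at a flat share and gave them independent widths. Its rates therefore do not cover lists whose promoters differ in CpG content or whose members share domains. The alternatives used other overlap rules, stricter −log10 q, the pooled list or 1 replicate's list alone, windows of 500 and 2500 bp, gaps of 0 and 3000 bp, only the 5'-most start site, other limits for wide and distal regions, and random sets matched on promoter CpG ratio. Domain width was also tested against 10000 random sets matched on the authors' peak signal or on the number of annotated start sites. Added after seeing the data were counting each domain once, using genes with 1 annotated start site, and an overlap of at least 50% of either peak.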

Results

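The data describe where H3K4me3 lay in the mouse heart at embryonic day 12.5, when the chambers, cushions and epicardium are forming. Both libraries belong to 1 group, replicates 1 and 2. Replicate 1 had 34351 peaks and replicate 2 had 34570, while the pooled list held 36608 and the replicated list 28105. After merging, these made 25212, 25796, 27292 and 23663 regions, which covered 40.3, 40.8, 45.0 and 41.6 Mb. Coordinates are on mm10, and the depth of the libraries is unknown because the lists carry no read counts.

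H3K4me3 in the replicated list was widest over genes that control heart development. The widest region, 21.6 kb on chromosome 14 (63231359 to 63252987), lay within Gata4, a zinc finger transcription factor of early heart development. It measured 21.7 ± 0.366 kb in the replicates' own lists (SD, n = 2), and 94.3% of it was intronic, around an internal start site, the 5'-most annotated start of the gene being at 63271692. Nkx2-5, a homeobox gene of cardiac progenitors, followed with 18.8 kb on chromosome 17 (26835887 to 26854656), of which 66.2% was intergenic. Hand2, a basic helix-loop-helix factor of the right ventricle, had 18.1 kb on chromosome 8 (57311652 to 57329786), a region that also holds the start of the antisense gene Hand2os1. Its width was 25.1 ± 0.177 kb in the replicates' lists, where short peaks missing from the replicated list joined it to the next region downstream.

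**Figure D1:**
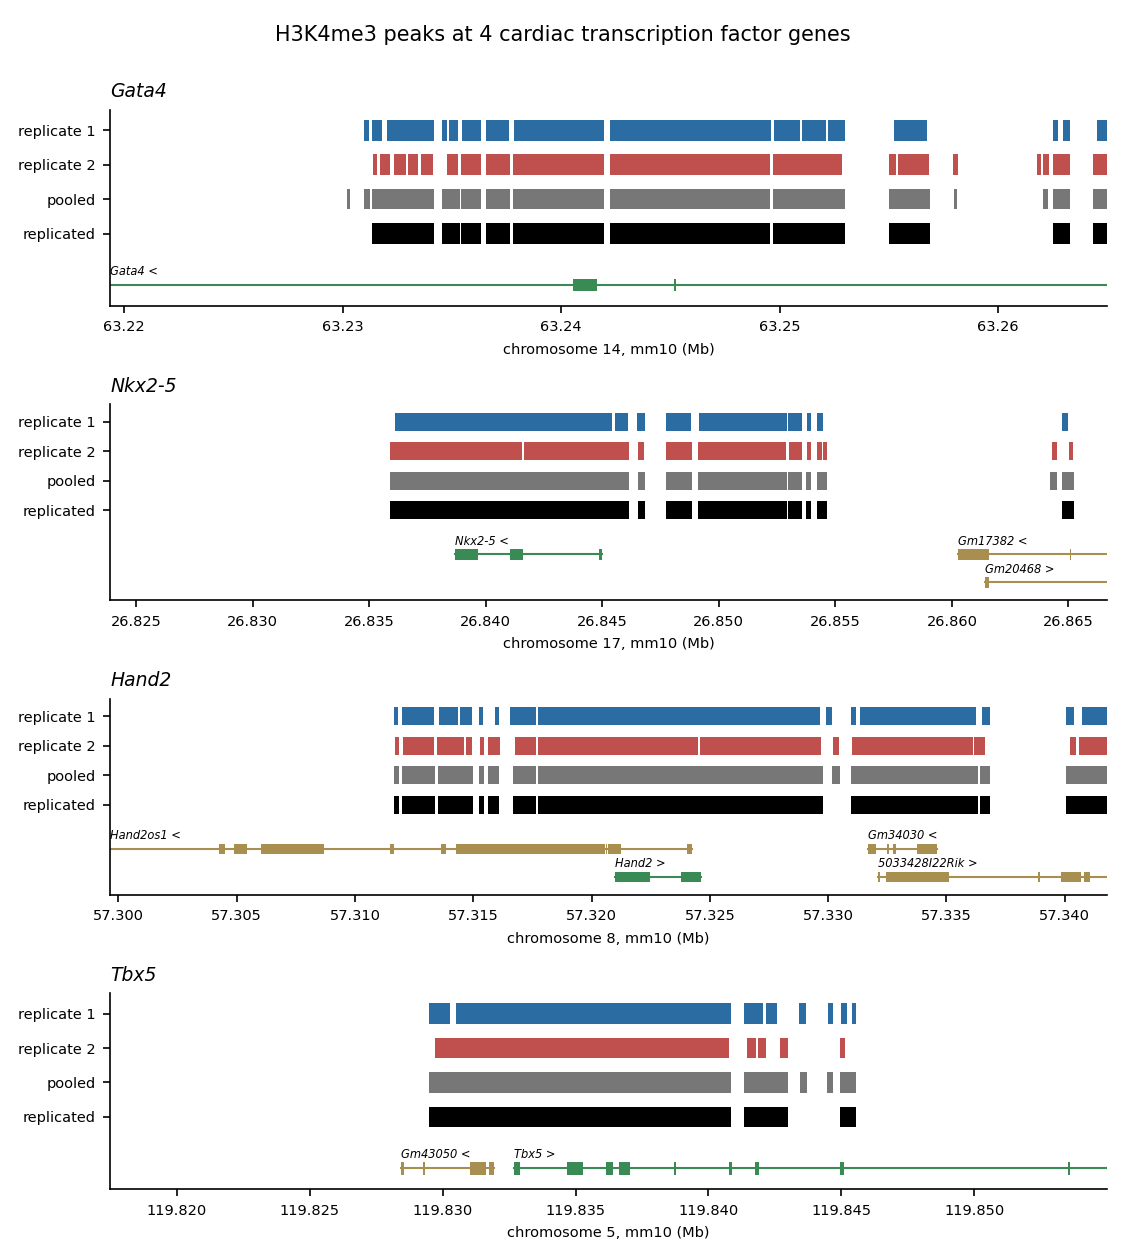
Peaks of the 4 deposited lists (y axis, 1 line per list) along the genome (x axis, Mb on mm10) at Gata4, Nkx2-5, Hand2 and Tbx5, with exons as boxes and genes as lines, protein-coding genes in green and others in brown, and arrowheads for the strand. The merged replicated regions span 21.6, 18.8, 18.1 and 13.5 kb, and both replicates have peaks across each of them.

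The replicates' lists were compared to see how far the mark could be called again in a second sample. Of the regions of replicate 1, 90.6% were overlapped by replicate 2, and of those of replicate 2, 88.4% were overlapped by replicate 1. Their mean was 89.5%, over the 2 directions of 1 comparison, so it has no spread over replicates. Random placement gave 3.39 ± 0.116% and 3.3 ± 0.124% (SD over 100 placements). The regions seen in 1 list only were narrow, with median widths of 214 and 219 bp against 1474 and 1483 bp for the shared ones, and weak, with median signals of 3.05 and 3.0 against 20.8 and 21.5.

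Replication followed the authors' signal. With the regions split into 5 equal classes by signal, in the weakest class 56.6% of replicate 1 and 48.0% of replicate 2 were overlapped by the other list. In the next class the shares were 96.2% and 94.1%, and in the upper 3 classes each was 100%.

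**Figure D2:**
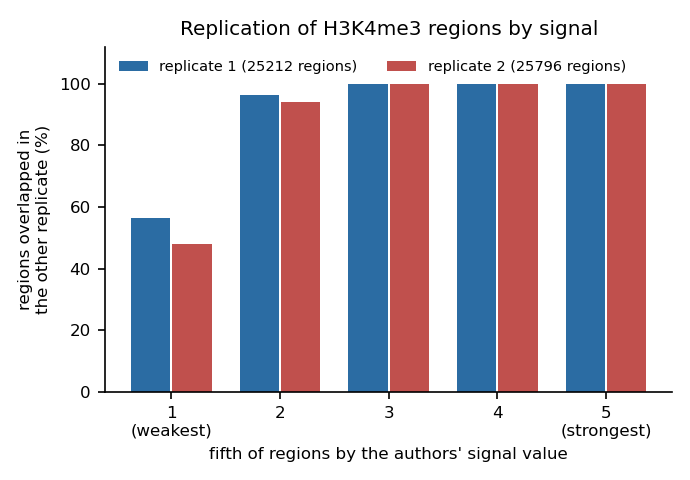
Percent of the merged regions of each replicate that overlap a region of the other (y axis), in 5 equal classes of the authors' signal value within the list (x axis), as bars for replicate 1 (blue) and replicate 2 (red) without error bars, since each bar is 1 list. The weakest class reaches 56.6% and 48.0%, and the 3 strongest reach 100%.

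The replicated list was a subset of the pooled list. All 28105 of its peaks were pooled peaks, 76.8% of that list, and the 8503 pooled peaks left out had a median −log10 q of 2.60 against 107.4 for those kept. With a pooled peak counted as covered when a list overlapped at least 50% of it, 78.1% were covered by replicate 1, 81.0% by replicate 2 and 68.6% by both. Of the replicated peaks, 1586 were not overlapped at all by both lists: 1540 met 1 list only and 46 met neither. These had a median signal of 3.13, against 17.8 for the others.

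Most of the marked sequence lay at promoters. Of the 23663 replicated regions, 14355 (60.7%) came within 1 kb of a protein-coding start site, against 4.71 ± 0.137% of random placements (SD over 100 placements). The share was lower in the replicates' own lists, 56.7 ± 0.780% (SD, n = 2). Regions at protein-coding start sites held 80.7% of the covered bases. A further 8.15% of the regions lay at other annotated start sites, 5.01% over exons, 10.3% in introns and 15.9% between genes. Requiring a −log10 q of at least 10 raised the share at protein-coding start sites to 68.4%.

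By this measure 14644 of 21853 protein-coding genes (67.01%) were marked. The replicates' lists marked 14686 and 14718 genes, a mean of 14702 ± 22.6 (SD, n = 2), with 14607 marked in both. The width of a gene's domain was close in the replicates, with a median SD of 0.104 kb and 79.4% of the genes within 1.2-fold. Across the 14607 genes, Spearman's correlation of the widths in the replicates was 0.937, a value across genes, which are not independent replicates. Widths of named genes are those of the replicated list, and the mean of the replicates' lists is added where their SD exceeded 1 kb or their mean differed from that width by over 1.2-fold.

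Every list of heart muscle, endothelial and cushion genes was almost wholly marked. All 25 cardiac transcription factors, 18 of 18 heart signalling genes, 23 of 23 endothelial and endocardial genes and 18 of 18 cushion mesenchyme and fibroblast genes had a peak. In the sarcomere list 21 of 22 were marked, Myom2 being the exception, and in the calcium handling and conduction list 21 of 22, all but Sln, which encodes the calcium pump regulator sarcolipin. Each of these shares exceeded that of other genes, which was 66.98% beside the sarcomere list, with adjusted p from 0.000254 for cardiac transcription factors to 0.00399 for the sarcomere and calcium lists (Fisher's exact test). When random sets were matched on promoter CpG ratio, the cardiac transcription factors (adjusted p = 0.221, permutation test) and heart signalling genes (0.210) no longer passed, whereas the sarcomere, calcium, endothelial and cushion lists did. All members of the first 2 lists were marked, so no higher share was possible. Their excess over the matched sets was 6.19 and 10.99 percentage points, so the matched test cannot tell an effect of CpG content from this ceiling. Over the 9 alternatives the adjusted p of these 2 lists ranged from 0.000229 to 0.221 and from 0.00146 to 0.210.

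Markers of several tissues other than heart were rarely marked. Of 16 leukocyte genes, including Adgre1, C1qa and C1qb, 0 were marked (adjusted p = 2.14e-07, Fisher's exact test). In each replicate's own list 1 of the 16 was marked, C1qb in replicate 1 and Cd68 in replicate 2, the latter named after its value was seen. Of 17 hepatocyte genes 2 were marked, the narrow domains of Apoa1 (1.15 kb) and Trf (0.84 kb), while Afp, Ahsg and Alb were unmarked, and the list of replicate 2 did not mark Apoa1 (adjusted p = 2.11e-05, Fisher's exact test). Of 17 germline genes 2 were marked, Dazl (0.78 kb) and Ddx4 (0.24 kb), while Acr, Mael and Piwil1 were unmarked (adjusted p = 2.11e-05, Fisher's exact test). Of 1134 olfactory receptor genes 3 were marked (0.265%), Olfr94, Olfr658 and Olfr1033, against 70.7% of other genes (adjusted p = 2.2e-299, Fisher's exact test, with p held at no less than 1e-300). Skeletal muscle genes were marked at 5 of 15, with Acta1 the widest at 3.03 kb and Myf5, Myh1 and Ckm, the last marked by the list of replicate 2, unmarked (adjusted p = 0.0151, Fisher's exact test). This last call was lost in the list of replicate 2 alone (adjusted p = 0.0672, Fisher's exact test) and against CpG-matched sets (0.265, permutation test), with a range of 0.00321 to 0.265 over 9 alternatives. The leukocyte, hepatocyte, germline and olfactory receptor shares stayed lower against CpG-matched sets. Over the 9 alternatives (Fisher's exact or permutation tests) the largest adjusted p were 0.01155, 0.01735, 0.00044 and 0.00044. Of the olfactory receptor genes, 1009 lay in the lowest 20% of genes by CpG ratio, where 3.18% of genes were marked.

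Neural and axial patterning genes were marked although the tissue was heart. All 18 neural patterning transcription factors had a peak (adjusted p = 0.00275, Fisher's exact test), as did 33 of 39 Hox genes (adjusted p = 0.0236, Fisher's exact test), with Hoxb3, Hoxb8 and Hoxc11 among the 6 without. Each replicate's own list marked 35 of the 39 Hox genes, Hoxb3 in both and Hoxb8 in replicate 2. Against CpG-matched sets the neural patterning call was lost (adjusted p = 1, permutation test), and the Hox share turned lower, with a difference of -8.93 percentage points (adjusted p = 0.0386, permutation test). With all 18 neural patterning genes marked, the matched excess could not exceed the 1.11 percentage points seen, so that test could not have shown a higher share. The Hox call was also lost at a −log10 q of at least 10 (adjusted p = 0.216) and with the 5'-most start site alone (0.295), both by Fisher's exact test, and was lowest at 2.66e-06 over 9 alternatives.

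Cell cycle genes (18 of 18), mitochondrial energy metabolism genes (20 of 20) and housekeeping genes (20 of 20) were all marked, with adjusted p of 0.00275, 0.00131 and 0.00131 (Fisher's exact test). None of these 3 lists passed against CpG-matched sets, where adjusted p was 1, 0.0678 and 1 (permutation test). Every member being marked, no higher share was possible, and the matched excess was 1.79, 12.6 and 1.41 percentage points. The matched tests therefore cannot tell an effect of CpG content from this ceiling. The shares of the epicardial (10 of 13), smooth muscle and pericyte (10 of 11), neural crest and Schwann cell (11 of 13), erythroid (12 of 17), neuronal differentiation (15 of 17), and lung and foregut (10 of 12) lists did not pass the test, with adjusted p from 0.0934 to 1 (Fisher's exact test). Unmarked among them were Mylk, Phox2b, Plp1, Dcx, Slc17a6, Sftpb and Sftpc. Against CpG-matched sets the smooth muscle and pericyte (adjusted p = 0.0308) and erythroid (0.00044) shares were higher (permutation test). The unmarked erythroid genes were globin genes: Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, and Hbb-y, which the list of replicate 2 marked. Apart from Hbb-y, these have near-identical copies, and how reads matching several copies were treated is not given, so their calls are uncertain. Whether this left them unmarked was not tested. In total, 11 lists had a higher and 5 a lower share than other genes.

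The 6 lists with the widest median domains were all of cell types or functions of the heart. The median domain of cardiac transcription factors was 6.44 kb, against 2.18 kb for other marked genes, and 6.34 ± 0.0106 kb in the replicates (SD, n = 2). The mean width percentile of these genes was 93.4 among all marked genes (adjusted p = 3.17e-05, permutation test). Beside Gata4, Nkx2-5 and Hand2, the widest were Tbx20 (16.1 kb), Tbx2 (16.0 kb), Gata6 (15.8 kb), Irx5 (13.9 kb) and Tbx5 (13.5 kb), transcription factors of the chambers and conduction tissue. Tbx2, Gata6 and Tbx5 varied between the replicates, at 12.9 ± 4.14 kb, 14.5 ± 1.44 kb and 14.7 ± 1.98 kb (SD, n = 2). The narrowest were Isl1 (2.71 kb), a factor of the second heart field, and Mef2a (2.44 kb).

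Sarcomere genes had a median of 5.79 kb and a mean percentile of 94.4 (adjusted p = 3.17e-05, permutation test). The widest were Myh7 (15.4 kb), Tpm1 and Myh6 (both 10.2 kb) and Actc1 (10.1 kb), which encode myosin heavy chains, tropomyosin and cardiac actin. Myh7 measured 13.7 ± 1.31 kb and Myh6 10.8 ± 1.17 kb in the replicates (SD, n = 2). Myl7, the atrial light chain, had 2.71 kb. Calcium handling and conduction genes had a median of 4.50 kb, led by Pln (8.03 kb), Jph2 (7.86 kb), Atp2a2 (7.80 kb) and Slc8a1 (6.74 kb). Heart signalling genes had 4.16 kb, with Bmp7 (7.71 kb), Notch1 (7.19 kb), Wnt11 (7.0 kb) and Vegfa (6.82 kb) widest, although Notch1 measured 4.58 ± 0.162 kb in the replicates (SD, n = 2). These lists had mean percentiles of 84.2 and 82.1, each with adjusted p = 3.17e-05 (permutation test).

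Among other cell types of the heart, cushion mesenchyme and fibroblast genes had a median of 4.34 kb, with Pdgfra (9.15 kb), Twist1 (7.39 kb), Prrx1 (6.86 kb) and Msx1 (6.81 kb) widest (adjusted p = 3.17e-05, permutation test). Endothelial and endocardial genes had 4.06 kb, led by Npr3 (9.65 kb) and Nfatc1 (9.47 kb), both markers of the endocardium, and by Tal1 (8.71 kb) and Fli1 (7.98 kb) (adjusted p = 9.5e-05, permutation test). Prrx1 measured 5.75 ± 1.45 kb and Fli1 7.29 ± 1.05 kb in the replicates (SD, n = 2). In the epicardial list Wt1 (8.41 kb), Tcf21 (7.37 kb) and Tbx18 (6.87 kb) had the widest domains. Sema3d (2.44 kb), Bnc2 (2.31 kb), Bnc1 (2.25 kb), Aldh1a2 (1.94 kb) and Krt19 (1.81 kb) were narrower, and Msln, Muc16 and Upk3b, the last marked by the list of replicate 1, were unmarked (median 2.36 kb; adjusted p = 0.357, permutation test). Upk1b, counted as marked, was marked by the list of replicate 2 but not by that of replicate 1. Wt1 measured 7.48 ± 1.19 kb and Tbx18 6.05 ± 1.05 kb in the replicates (SD, n = 2).

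**Figure D3:**
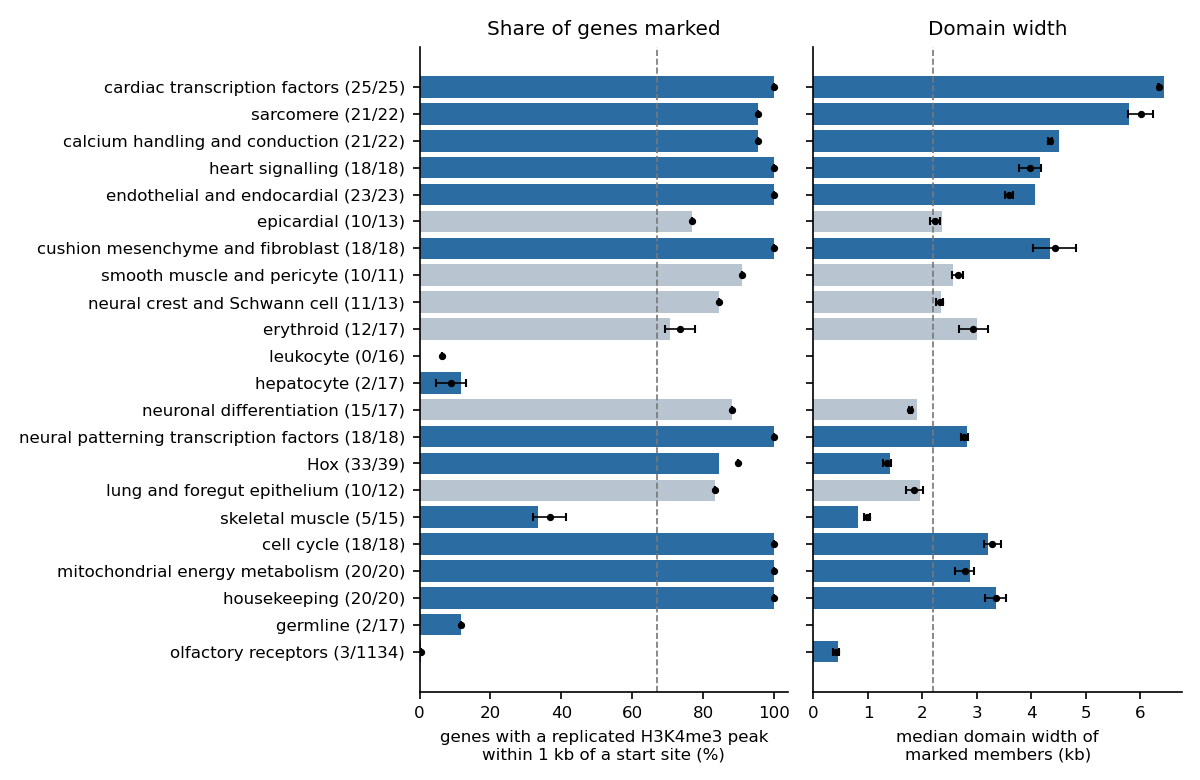
Percent of each gene list marked (left) and median domain width in kb of its marked members for lists with at least 3 (right), with lists on the y axis and marked over all members in brackets; bars are the replicated list (dark where adjusted p is under 0.05), points the mean ± SD of 2 replicates' lists, and dashed lines all protein-coding genes (67.01%) or all marked genes (2.19 kb). Cardiac transcription factors reach 6.44 kb and Hox genes 1.41 kb.

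Of the lists outside the heart, neural patterning factors had a median of 2.83 kb (adjusted p = 0.00337, permutation test), with Dlx2 (6.68 kb) and Sox3 (5.95 kb) widest. They measured 4.42 ± 0.156 kb and 4.47 ± 0.001 kb in the replicates (SD, n = 2). This call was lost with a gap of 0 bp (adjusted p = 0.817), at a −log10 q of at least 10 (0.114), with the 5'-most start site (0.0704) and against CpG-matched sets (0.0964), all by permutation test, and was lowest at 3.17e-05 over 12 alternatives. It held against sets matched on peak signal (mean percentile 70.7 against 31.0 expected; adjusted p = 0.000271) and on the number of annotated start sites (0.00432), both by permutation test. Hox domains were narrow, at a median of 1.41 kb (adjusted p = 3.17e-05, permutation test), with Hoxa1 (4.75 kb) and Hoxb2 (3.40 kb) widest. A gap of 3000 bp ended this call (adjusted p = 0.166, permutation test), and so did sets matched on the authors' peak signal, where the mean percentile was 25.3 against 22.7 expected (0.562, permutation test). The Hox call held against sets matched on promoter CpG ratio (adjusted p = 0.000271) and on the number of annotated start sites (0.0002375), both by permutation test. Skeletal muscle (0.814 kb; adjusted p = 0.0217, permutation test) and olfactory receptor genes (0.455 kb; adjusted p = 0.00182, permutation test) were narrower too, but neither passed against CpG-matched sets (0.136 and 0.0964, permutation test) or against sets matched on peak signal (0.852 and 0.139, permutation test). Both stayed narrower than sets matched on the number of annotated start sites (adjusted p = 0.0365 and 0.00285, permutation test). The skeletal muscle call was also lost in the list of replicate 1 alone (0.0525), with a window of 500 bp (0.0785) and with the 5'-most start site (0.0944). Neuronal differentiation genes, at 1.90 kb, missed the threshold (adjusted p = 0.0505, permutation test; 0.0271 to 0.752 over 12 alternatives), with Gad2 (2.71 kb) and Neurog2 (2.66 kb) widest. They were narrower than sets matched on the number of annotated start sites (adjusted p = 0.0365, permutation test). Against sets matched on promoter CpG ratio (0.105) or peak signal (0.263) they did not pass (permutation test).

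Broadly expressed genes were also wider than other marked genes. Housekeeping genes had a median of 3.35 kb (adjusted p = 8.1e-05, permutation test), with Gapdh (6.93 kb) and Eef2 (6.10 kb; 4.71 ± 0.896 kb in the replicates, SD, n = 2) widest, and cell cycle genes 3.21 kb (adjusted p = 0.0011, permutation test), with Ccnd2 (8.14 kb) and Ccnd1 (6.32 kb) widest. Mitochondrial energy metabolism genes had 2.87 kb (adjusted p = 0.0386, permutation test), led by Cpt1a (4.57 kb) and Ppargc1a (4.44 kb), a call lost in the list of replicate 1 alone (adjusted p = 0.0696, permutation test) and with the 5'-most start site (0.11). Erythroid genes (3.0 kb), smooth muscle and pericyte genes (2.56 kb), neural crest and Schwann cell genes (2.33 kb), and lung and foregut genes (1.95 kb) did not pass the test, with adjusted p from 0.149 to 0.611 (permutation test). The erythroid list was wider in the pooled list (adjusted p = 0.0319), and the lung and foregut list was narrower with a gap of 0 bp (0.0393), both by permutation test. Against CpG-matched sets the erythroid (0.0019) and the smooth muscle and pericyte (0.0431) lists were wider (permutation test). Against sets matched on peak signal the erythroid (0.000475), smooth muscle and pericyte (0.0148), and neural crest and Schwann cell (0.0169) lists were wider (permutation test). Of the 19 lists tested, 10 were wider and 3 narrower.

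The widest 5% of start-site domains, 663 of 13242, were at least 4.91 kb wide and held 783 genes. They held 18 of the 25 cardiac transcription factors (72.0%) and 13 of the 21 marked sarcomere genes (61.9%), against 5.23% and 5.27% of other marked genes (adjusted p = 7.49e-17 and 3.8e-11, Fisher's exact test). Cushion mesenchyme genes (8 of 18), calcium handling genes (8 of 21), heart signalling genes (7 of 18) and endothelial genes (7 of 23) were over-represented as well, with adjusted p from 1.22e-05 to 0.000491 (Fisher's exact test). The epicardial list, through Wt1, Tcf21 and Tbx18 (3 of 10; adjusted p = 0.0413, Fisher's exact test), and the neural crest list, through Tfap2a (8.41 kb), Ets1 (6.71 kb) and Ednrb (5.69 kb) (3 of 11; 0.0478), passed narrowly. Tfap2a measured 6.58 ± 0.125 kb in the replicates (SD, n = 2). The neural crest call was lost in either replicate's list alone (adjusted p = 0.0502 and 0.0512, Fisher's exact test). Of the alternatives, it held only at a −log10 q of at least 5 and with a window of 500 bp. The epicardial call was lost in the pooled list (0.0512, Fisher's exact test), with a window of 2500 bp, with gaps of 0 and 3000 bp and at the widest 10%. Over 12 alternatives the adjusted p ranged from 0.0361 to 0.764 for the neural crest list and from 0.0217 to 0.764 for the epicardial list. At the widest 1% the cushion (0.058) and heart signalling (0.381) calls were lost too. Calls were gained for neural patterning with a gap of 3000 bp (0.00406) and at the widest 10% (0.026), and for housekeeping at the widest 10% (0.0394). In all, 8 of 21 lists tested were over-represented.

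Other genes among the 20 with the widest domains were Meis2 (17.4 kb) and Meis1 (14.3 kb), homeobox cofactors, Nfib (14.5 kb), a nuclear factor I gene, Bahcc1 (14.4 kb), Kdm6b (13.9 kb), which encodes a histone H3 lysine 27 demethylase, Smad7 (13.4 kb), an inhibitor of transforming growth factor beta signalling, Tnrc18 (13.3 kb) and Qk (13.2 kb), which encodes an RNA-binding protein. A region of 17.8 kb on chromosome 10 (80136281 to 80154101) was shared by Atp5d, Cbarp and Midn. It was not held as 1 domain in the replicates' lists, where the width was 5.80 ± 2.52 kb (SD, n = 2). Kdm6b likewise varied, at 10.4 ± 4.29 kb, and so did Bahcc1 (13.3 ± 1.36 kb), Qk (12.3 ± 1.13 kb) and Tnrc18 (12.4 ± 1.04 kb) (SD, n = 2), while Meis2 and Meis1 did not, at 17.4 ± 0.047 kb and 14.2 ± 0.037 kb (SD, n = 2).

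Among genes alone in their region, H3K4me3 reached farther into the gene than upstream. Over 10422 such genes, the mark extended a mean of 1578 bp downstream of the 5'-most start site in the region and 625 bp upstream. The mean difference was 953 bp (p = 1e-05, permutation test, the smallest these permutations can give). In 91.3% of the genes the downstream side was longer. The difference was 960 ± 2.05 bp in the replicates' lists (SD, n = 2). In the 453 such genes of the widest 5%, the means were 4289 bp downstream and 1272 bp upstream. Measuring from the 5'-most start site in itself shortens the upstream side. In genes with 1 annotated start site, where that choice does not arise, the difference was 887 bp (p = 1e-05, permutation test). Regions that also hold a start site of another gene, such as a divergent neighbour, were left out, so these values do not cover them.

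**Figure D4:**
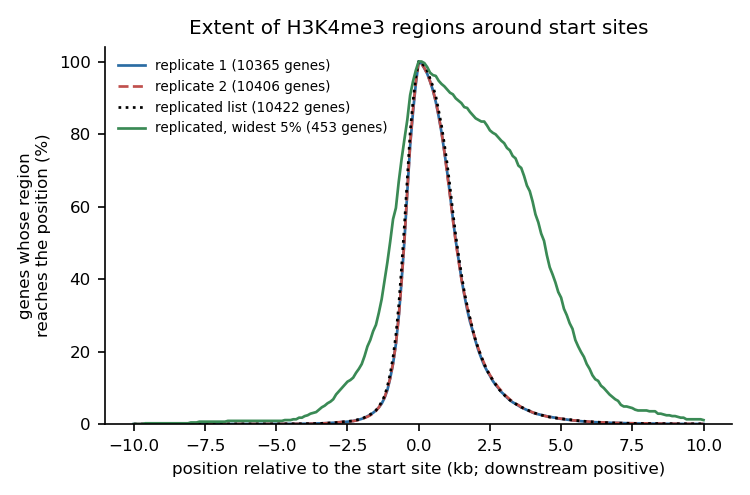
Percent of genes whose H3K4me3 region reaches each position (y axis) around the 5'-most start site within it (x axis, kb, downstream positive), as lines for replicate 1, replicate 2, the replicated list and the replicated genes in the widest 5%. At 1 kb the replicated list holds 71.8% of genes downstream and 13.9% upstream, and the lines of the replicates overlie each other.

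Marked genes had CpG-rich promoters. The median CpG ratio was 0.548 in marked and 0.165 in unmarked genes (p = 1e-05, permutation test, the smallest these permutations can give). With genes split into 10 equal classes by CpG ratio, the share marked was 1.28% in the lowest class, 24.0% in the third, 60.8% in the fourth, 88.1% in the fifth and 99.6% in the highest. Median domain width was 0.983 kb in the lowest class and 2.89 kb in the highest.

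Away from promoters, 3678 replicated regions (15.5%) lay over 10 kb from any annotated start site. They were narrower than regions at protein-coding start sites, with a median of 0.590 kb against 2.06 kb, and weaker, with a median signal of 5.22 against 37.0. Of these, 60.9% were intergenic and 31.3% intronic. The widest, 6.86 kb on chromosome 11 (119052318 to 119059181), was intergenic with Cbx8 as the nearest protein-coding gene, and measured 6.61 ± 0.0933 kb in the replicates (SD, n = 2). Introns of Bcl11b (4.96 kb), Foxp1 (4.55 kb) and Nav2 (4.46 kb) held 3 of the next 4, and a 4.82 kb intergenic region lay nearest to Zfp217. The Bcl11b region measured 3.3 ± 2.13 kb in the replicates (SD, n = 2). The other 5 of the 10 widest lay nearest to Olfr1368 (4.29 kb), Hfe2 (4.22 kb), Zfp64 (3.96 kb), Ppara (3.73 kb) and 4933402J07Rik (3.60 kb). The Zfp64 and 4933402J07Rik regions measured 2.64 ± 1.07 kb and 2.36 ± 1.52 kb in the replicates (SD, n = 2).

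Few genes were marked in 1 replicate only: 79 in replicate 1 and 111 in replicate 2, which are 0.538% and 0.754% of the genes marked in each. None belonged to the cardiac transcription factor, sarcomere, calcium, heart signalling, endothelial or cushion lists. In replicate 1 the strongest were Vpreb1 (signal 36.3), Gm867 (23.2), Amh (21.9), Tymp (13.7) and Art1 (12.1), and in replicate 2 Iqcn (39.8), Plin1 (28.8), Rs1 (28.1), Prickle4 (26.1) and Lck (18.6). Each of these 10 genes had its region overlapped by the other replicate's list, in which no peak came within 1 kb of a start site of the gene. By contrast, 70 of the 79 and 97 of the 111 genes had no peak of the other replicate in their region, and these regions had a median signal of 3.04 and 3.0, against 34.0 and 34.7 for genes marked in both.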

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

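The test of neural cells in the dissected tissue was chosen after the result was seen. The other tests here were planned before their values were known.

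A signal lay outside the sequence used for regions and genes: 11 replicated peaks were on unplaced or unlocalized scaffolds, 6 of them within 1 kb of an annotated start site, including those of Vamp7 and Tmlhe, and replicates 1 and 2 had 13 and 12 such peaks.

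Members of the cardiac transcription factor, sarcomere, calcium handling, heart signalling, endothelial and cushion lists lay in wide domains. Promoter CpG content, peak strength and the number of annotated start sites were each tested by drawing random sets matched on them. All 6 lists stayed wider than sets matched on promoter CpG content, all 6 than sets matched on peak strength, and all 6 than sets matched on the number of annotated start sites (each raw p = 0.0001, permutation test, the smallest that 10000 random sets can give). This argues against each of these properties as the whole reason for the widths. Staying wider was not particular to the heart lists. Housekeeping, cell cycle and mitochondrial energy metabolism genes also did so against each kind of matched set. Their largest adjusted p were 0.0057, 0.0177 and 0.0476 (permutation test). No biological explanation was tested for the wide domains of the 6 lists, since the samples form 1 group.

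The 18 neural patterning factors were all marked, in domains wider than those of other marked genes. Against sets matched on promoter CpG content their mean width percentile, 70.7 against 60.4 expected, was no longer beyond chance (p = 0.0698, permutation test). Unmatched sets had 50 expected, so CpG-rich promoters may account for part of the width. Whether they account for the rest cannot be told from 18 genes. The list was wider than sets matched on peak strength (31.0 expected). Neural cells in the dissected tissue would bring neuronal genes. Of the 17 neuronal differentiation genes, a list that shares no member with another list, 15 were marked (88.2% against 66.99% of other genes). This share did not pass its test (adjusted p = 0.0934, Fisher's exact test), and Dcx was among the unmarked. The list's mean width percentile was 34.6, its widest members being Gad2 (2.71 kb) and Neurog2 (2.66 kb). That percentile lies below random marked genes without passing the threshold (adjusted p = 0.0505, permutation test). It lies above the 26.8 expected for sets matched on peak strength and below the 46.58 for CpG-matched sets, again without passing (adjusted p = 0.263 and 0.105, permutation test). Against sets matched on the number of annotated start sites (50.75 expected) the list was narrower (adjusted p = 0.0365, permutation test). It was narrower too with a gap of 0 bp (0.0271) and in the list of replicate 1 alone (0.0295), both by permutation test. Progenitors without neuronal genes would not show in this list, so a share of neural cells stays open. Which of these genes the heart itself expresses was not measured.

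Of the replicated regions, 3678 lay over 10 kb from any annotated start site. Unannotated CpG-rich promoters are a candidate explanation for part of them. The median CpG ratio of these regions was 0.4255, nearer to the 0.590 of regions at start sites than to the 0.148 of a random placement. That last value came from 1 placement only, so it has no spread. Marked promoters were CpG-rich in these data, so the ratio does not separate unannotated promoters from other CpG-rich sequence. Start sites missing from the annotation reached 9.95% of the regions, which lay within 1 kb of a RefSeq start site against 1.19 ± 0.169% of random placements (SD over 100 placements), so they remain open for a small part. For weak peaks near the calling threshold, 48.5% of the distal regions were in the lowest 20% of regions by the authors' signal. That is a rank and does not measure nearness to the threshold. Distal regions numbered 3290 at a −log10 q of at least 5 and 2427 at 10, so weak calls remain open for a part.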

How the results depend on the processing

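Counting each domain once, genes with 1 annotated start site and 50% of either peak were alternatives chosen after seeing the data. The downstream extension (766 to 1024 bp) and the CpG difference (0.382 to 0.448) kept their direction and p = 1e-05, the smallest permutations can give, under every alternative run for them, and the marked genes numbered 14057 to 14868. The adjusted p for width of the cardiac transcription factor and sarcomere lists was at most 0.000271 under the 12 alternatives (permutation tests). Depth is unknown, so what it limits could not be measured. No paired analysis was possible because there is 1 group.

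The share of regions at protein-coding start sites was 56.2% to 57.3% when a replicate was left out, 53.5% or 53.6% with the 5'-most start site or the pooled list, 62.9% and 68.4% at a −log10 q of at least 5 and 10, and 62.8% with a window of 2500 bp. Distal regions numbered 2427 at a −log10 q of at least 10 and 610 at over 50 kb. Against CpG-matched sets 6 lists had a higher share and 1 was narrower, with the 5'-most start site 1 was narrower, with a gap of 0 bp 5 were, and at the widest 1% 5 were over-represented. Overlap of replicates 1 and 2 was 88% and 84.9% when at least 50% of a region was needed, 84.4% and 82.5% for reciprocal 50%, and 85.1% and 82.9% for single peaks. It was 95.9% and 93.7% at a −log10 q of at least 5, and 90.1% for replicate 2 at 2.

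Pooled peaks were covered by replicate 1, replicate 2 and both at 81.2%, 83.3% and 72.6% with 1 bp, at 63.4%, 67.8% and 51.2% with 80% of the pooled peak, at 80.8%, 83.0% and 72.4% with 50% of either peak, and at 82.8%, 85.3% and 78.2% at a −log10 q of at least 5. In the replicated list were then 97.1%, and 82.6% at a −log10 q of at least 2, where both replicates covered 70.8%. Needing 50% of the region, the 5 classes by signal, weakest first, overlapped at 47.9%, 92.8%, 99.4%, 99.9% and 99.96% in replicate 1, and at 37.9%, 87.2%, 99.4%, 99.9% and 99.98% in replicate 2.

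Differences from other genes that turned direction, in percentage points of the share marked, were -13.1 for erythroid at a −log10 q of at least 10, and -2.45 for neural crest and -8.93 for Hox against CpG-matched sets. In mean width percentile they were -2.62 for smooth muscle, -2.23 for neural crest and -15.2 for erythroid with a gap of 0 bp, 13.7 for lung with a gap of 3000 bp and 3.98 for lung with a window of 2500 bp. In percentage points within the widest domains, neural patterning gave -5.36 and -5.40 with a replicate left out and -1.11 at the widest 1%, as did housekeeping. At a −log10 q of at least 10, smooth muscle gave 4.645 and housekeeping -0.359, and lung gave 4.63 with a window of 2500 bp. With a gap of 0 bp, smooth muscle gave 4.92, erythroid -5.085 and mitochondrial 4.93. With a gap of 3000 bp, neuronal gave 0.392, Hox 5.86, lung 13.7 and mitochondrial 3.73, and at the widest 10% smooth muscle and lung gave 9.36 and mitochondrial 4.36. Except for the Hox share, none of these differences passed its test in either setting. For all of these the cause was not tested. Of the other list tests, those of the share marked kept their outcome 183 times, lost a call 10 times and gained one 2 times. Those of width kept their outcome 204 times, lost a call 12 times and gained one 6 times. Those of the widest domains kept their outcome 215 times, lost a call 17 times and gained one 3 times. Kept outcomes include lists that passed in neither setting, so they are not counts of calls that held. With the 5'-most start site the olfactory receptor width gave no value, and with a window of 2500 bp the germline list could be tested and was narrower. Named-gene widths stayed within 1 SD of the replicates in 529 cases and moved further in 402.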

Other observations

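The genes named here were chosen after their values were seen, and the test of low-CpG promoters was chosen, with its 3 lists, after the result was seen. The test of distal regions near heart genes was planned.

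Annotated start sites other than those of protein-coding transcripts held wide domains too. Of the 1929 regions in this class, the widest was 12.4 kb at 5430431A17Rik on chromosome 7 (44472414 to 44484807), and it measured 12.3 ± 0.209 kb in the replicates (SD, n = 2). Malat1, a nuclear long noncoding RNA, had 9.78 kb on chromosome 19 (5794616 to 5804395) and 10.1 ± 0.541 kb in the replicates, and Neat1, the RNA scaffold of paraspeckles, had 8.10 kb and 7.59 ± 0.146 kb (SD, n = 2). The host locus of Mir1a-1, a microRNA of heart and skeletal muscle, had 8.60 kb on chromosome 2 (180385341 to 180393940) and 8.49 ± 0.115 kb (SD, n = 2).

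Both sexes were present in the pools, per the labels, and genes of both sex chromosomes were marked. Xist, the RNA that coats the inactive X chromosome, had 3.65 kb on the X chromosome (103480173 to 103483821), and 3.62 ± 0.000707 kb in the replicates (SD, n = 2). The Y chromosome held 6 replicated regions, and Eif2s3y (1.90 kb), Ddx3y (1.81 kb), Uty (0.994 kb) and Kdm5d (0.782 kb) were marked.

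Promoters poor in CpG were rarely marked. In the lowest 20% of genes by CpG ratio, 139 of 4371 (3.18%) were marked. Of the 16 genes there from the sarcomere, calcium handling and erythroid lists, 12 were marked (75%): 5 of 6 sarcomere genes, 1 of 1 calcium handling gene and 6 of 9 erythroid genes. Of the other lists, 2 of 2 endothelial, 1 of 1 cushion and 1 of 4 hepatocyte genes there were marked. The remaining lists with members there had 0 marked: 6 leukocyte, 4 skeletal muscle, 2 epicardial, 1 neural crest, 1 germline and 1009 olfactory receptor genes. Because the 3 lists were picked after the marked genes were seen, these counts decide nothing about whether heart muscle and blood genes stand apart. The widest domains in this lowest 20% lay at Myh6 (10.2 kb), Mybpc3 (7.81 kb), Slc4a1 (7.78 kb), which encodes the anion exchanger of red blood cells, and Tnnc1 (7.45 kb). Slc4a1 and Tnnc1 varied between the replicates, at 6.02 ± 2.14 kb and 8.03 ± 1.18 kb (SD, n = 2).

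Regions over 10 kb from any start site could be distal elements of heart genes. The test gave no sign of that: the nearest protein-coding gene was in the cardiac transcription factor, sarcomere, calcium handling or heart signalling list for 58 of 3678 regions (1.58%), and random placements gave 1.44 ± 0.188% (SD over 100 placements), with a range of 0.952% to 1.88%. The nearest gene need not be the one a region acts on.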
